A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

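Total RNA of Escherichia coli K-12 MG1655 was measured in 8 samples, cells with pSDP10 and cells with the empty vector pMMB206 at 0, 30, 90 and 180 min. Per the labels' protocols, cells grew in M9 glucose medium at 37 °C and were induced with 1 µM IPTG at 30 °C, and 500 ng of RNA was reverse transcribed from random hexamers, amplified with T7 RNA polymerase and labelled with Cy3. Groups and times came from the sample titles, and every group held 1 sample, so p-values come from fits that pool the spread over arrays. Per the file headers, the spot intensity values were extracted by Agilent Feature Extraction 10.7.3.1 from a custom 15744-spot array, which subtracted background and, on 6 of the 8 arrays, removed a multiplicative trend over the slide. The trend surface averaged 0 in the headers of the pSDP10 array at 180 min and the vector array at 0 min. The files of the vector arrays hold rounded values. The deposited value table of the authors holds log2 values per gene. Set against the scanner values, across genes, they were the signal on a log2 scale shifted to the 75th percentile, without centring of genes (r = 0.999 or more, column medians −0.365 to −0.336 for pSDP10 and −1.07 to −0.807 for the vector). They were used as an alternative, and the authors' rule for combining probes stays unknown. Other steps of the authors are not given in the sources used here.

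Spots were joined across arrays by feature number. Control spots were left out, as were 42 spots with outlier flags, while saturated spots were kept. Of 15208 non-control probes 10828 were coding, 2190 sense and 2190 antisense to non-coding regions. The array's gene names were matched through gene numbers, and 2 through synonyms, to the RefSeq table of assembly ASM584v2, used for names only. Of 4209 coding names 4053 matched, and 156 coding names without a gene were left out. The coding probes carried 4211 gene symbols, slightly more than names, and 4055 genes were compared. Coordinates are those of the array's annotation, an older version of the MG1655 chromosome. The level of a gene was the mean of its coding probes well above background on at least 2 arrays, on the scale of log2 processed signal minus the array's 75th percentile over non-control probes. All 10452 named coding probes passed that filter. The lac operon, the lacI gene and the orf306 insert were not analysed here, so the induction itself was not checked at the RNA level. For 12 genes a probe sequence also stood under another gene.

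Genes were tested in limma 3.58.1 (R 4.3.3) with lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. An additive fit of plasmid and time, with 3 residual degrees of freedom, gave the changes at each time in both plasmids and the mean difference between plasmids. A fit that added plasmid by after-induction, with 2 residual degrees of freedom, gave the difference between plasmids in the change after induction. A block for the slide could not be fitted in the plasmid comparison, since slide and plasmid coincide. Differences of single arrays (each time against 0 min between plasmids, and 0 min itself) were given as values without a test. They were counted at 2-fold or more with all probes of the gene on 1 side of 0. Of the 35 gene lists fixed before the data were examined 33 had measured genes. They were tested with camera (preset correlation 0.01, then an estimated correlation) and fry, adjusted over the lists of a contrast. For untested values the list's median was placed among 10000 random lists of the same size matched on mean signal. These were drawn gene by gene, without regard to correlation between genes.

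Named genes followed a rule fixed before the data were examined. It takes for each time contrast the 6 highest and 6 lowest called genes, and for the plasmid contrast and the contrast of changes the 12 highest and 12 lowest called genes, filled by size among genes of 1 sign at every time where fewer pass. It adds the 5 highest and 5 lowest genes with at least 2 agreeing probes for each untested comparison, up to 4 of the largest members of each list described, and the hca and mhp genes. Lists to describe were picked after their values were seen. The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, median scaling, cyclic loess, the authors' table, other probe filters and summaries, a mean-variance trend, other fold minima and designs, and leaving out each array in turn. Scaling to antisense probes of non-coding regions, and times up to 90 min only, were added after seeing the data. The fits were tested on simulated data with 200 genes changed by log2 sizes of 1, 2 and 4. The fit for the changes at 180 min called 68.7%, 89.6% and 95.5% of these, with 7 false calls, and that for the plasmid comparison 86.6%, 94.0% and 98.5%, with 11 false calls. For the contrast of changes there were 4 false calls. With 200 genes changed at once the adjusted threshold is easier to pass, so these shares can be too high for the measured data. The noise took each gene's residual SD from the additive fit, also for the contrast of changes. The figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The number of arrays limits the precision.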

Results

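The response of Escherichia coli K-12 MG1655 to Orf306, an esterase encoded on the organophosphate degradation island of a Sphingobium strain, was followed with single-colour expression arrays. Cells carried either pSDP10, in which orf306 stands under the tac promoter of the broad-host-range vector pMMB206, or pMMB206 itself. RNA was taken before induction with IPTG (0 min) and 30, 90 and 180 min after it, and each of the 8 combinations of plasmid and time was measured on 1 array. No combination had a second array, so the number of arrays limits the precision, and a value of 1 plasmid at 1 time has no replicate check. Each plasmid lay on its own slide, so plasmid and slide cannot be told apart in a direct comparison of levels. All 4 pSDP10 arrays had a narrower range of signal than the vector arrays. The 95th percentile of non-control probes was 9.06 to 11.7 times the 5th percentile on the pSDP10 arrays and 44.0 to 68.2 times on the vector arrays. Over 99.4% of the 15208 non-control probes were well above background on every array, and the levels of 4055 genes were compared. Levels are log2 signals relative to the array's 75th percentile.

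**Figure D1:**
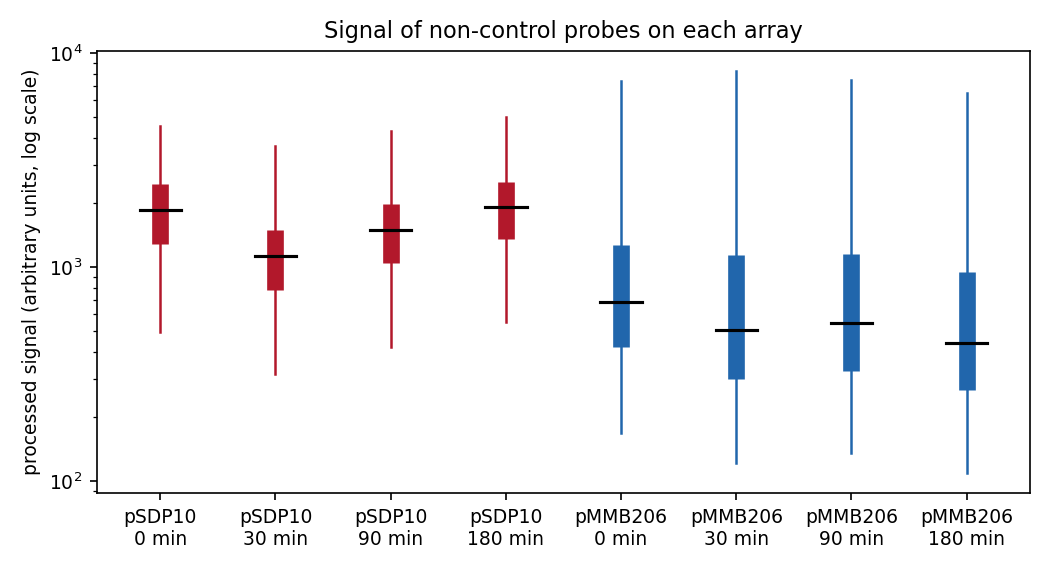
Processed signal of the 15208 non-control probes on each array (arbitrary units, log axis), with the plasmid and time on the horizontal axis. Thin lines span the 5th to 95th percentiles, thick bars the 25th to 75th and black marks the median; the medians lie between 1121 and 1898 on the pSDP10 arrays and between 443 and 688 on the vector arrays.

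The first question was which genes responded to induction of orf306 beyond the response of the vector-only cells, read as the change since 0 min in pSDP10 minus that in the vector. The plasmids differed at 0 min, so a positive difference of changes can go with a lower level in pSDP10. Ribosomal protein genes, for example, had a median of −2.80 (pSDP10 minus vector) at 0 min. At 30 min the genes for catabolism of phenylpropionate and cinnamate, the hca and mhp genes, stood out. All 15 had a positive difference of changes, with a median of 1.30 on the log2 scale, at percentile 100 of random lists of the same size and signal, whose median was 0.25. Random lists were drawn gene by gene, while genes of 1 operon or regulon can move together. The percentiles given here and below can therefore be too extreme, and they are not p-values. For the hca and mhp list the median change was 0.96 in pSDP10 and −0.48 in the vector, against −0.0030 and −0.17 for all 4055 genes. The difference was 2.38 for mhpC, 2.26 for mhpA, 2.20 for hcaF and 1.74 for hcaB. For some genes the vector part is not exact, since mhpC, at −1.53 at 0 min and −2.09 at 30 min, and mhpB, mhpF and mhpR lay in the vector at or below the medians of probes antisense to non-coding regions (−1.50 and −1.86). In pSDP10 mhpC went from −0.43 to 1.39, where these medians were −0.89 and −0.87. The hca and mhp list was chosen in the knowledge that the study discusses these operons, so it is not independent evidence. The members did not move alike. The structural genes mhpA to mhpE, at positions 367835 to 374105 of the chromosome as the array annotation numbers it, and hcaE, hcaF, hcaC and hcaB, at 2667054 to 2670059, had differences of 1.01 to 2.38 apart from mhpF at 0.58, whose probes had both signs. The last gene, hcaD, was at 0.84. The regulators mhpR and hcaR and the transporters mhpT and hcaT lay between 0.41 and 0.51.

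**Figure D2:**
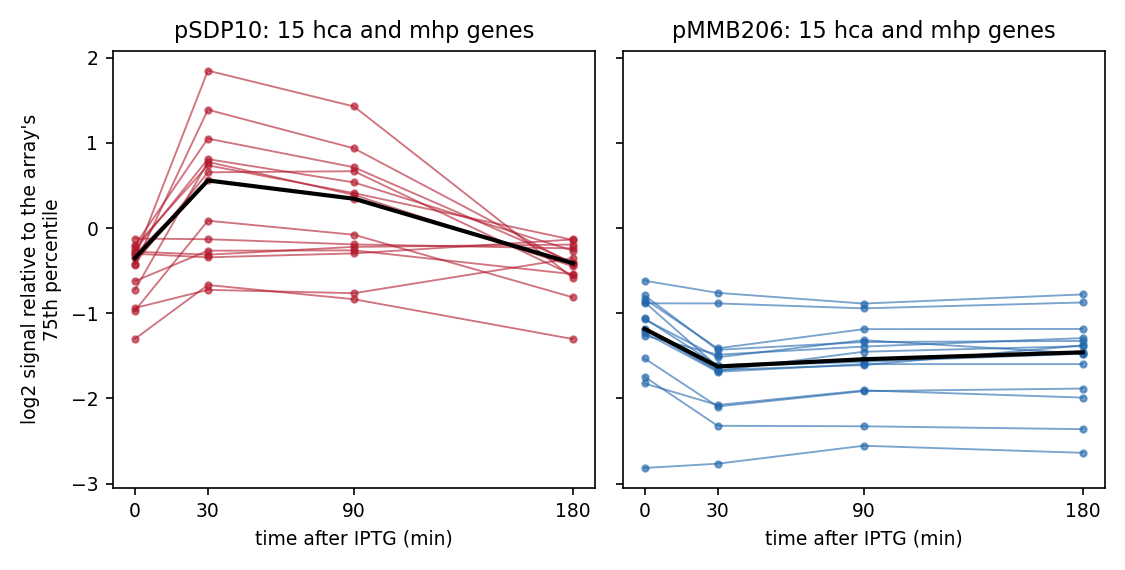
Levels of the 15 hca and mhp genes (log2 signal relative to the array's 75th percentile) by time after IPTG, pSDP10 on the left and pMMB206 on the right, 1 array per point. Thin lines are genes and the black line is their median; hcaF went from −0.35 at 0 min to 1.85 at 30 min and −0.59 at 180 min in pSDP10 and stayed between −0.94 and −0.87 in the vector.

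Also at 30 min, the multiple antibiotic resistance operon differed, with marB at 2.61, marA, a transcriptional activator of efflux genes, at 2.37 and its repressor gene marR at 1.25. The level of marA in pSDP10 was 0.26 at 0 min, 2.77 at 30 min, 2.84 at 90 min and 0.06 at 180 min, while its vector levels lay between −0.69 and −0.30. The rest of the efflux list did not follow. Of its 16 genes 3 differed by 2-fold or more, and the list's median of 0.26 was at percentile 83.1. The largest positive differences were those of lysP, the lysine permease, at 2.95, followed by marB, the translocon gene secY at 2.55, the prophage gene ymfD at 2.51 and mhpC. Ribosomal protein genes had a median of 0.85 (percentile 99.99), with 19 of 53 at least 2-fold higher, led by rpsF at 2.38, rpmJ at 2.08, rpsM at 2.06 and rplJ at 2.05. All 44 genes for uptake of alternative carbon sources had a positive difference (median 0.73, percentile 100), with glpQ at 1.98 and glpF at 1.59, both of glycerol metabolism.

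The largest negative differences at 30 min were those of yodD at −3.65, ytjA at −2.97, znuA, the zinc-binding component of a zinc importer, at −2.76, the trehalose synthesis gene otsA at −2.75 and the isocitrate lyase gene aceA at −2.61. Saturated spots were kept at their value, so the values of genes that had them are not exact. Among the genes named for single times since induction these were, over the 4 pSDP10 arrays, 9 spots of acs, 4 of rpsM, 3 each of glpF and purL, 2 each of yodD, secY and rpmJ, and 1 each of prpB, astC, clpX and hdeA. Over the 4 vector arrays they were 8 of clpX, 4 of serA, 3 each of znuA, secY, rpmJ and dnaK, 2 each of zinT and hdeA, and 1 each of rpsM and ynfE. Of 23 genes of the RpoS general stress response 18 had negative differences (median −0.35, percentile 0.0), with osmY at −2.30, osmC at −1.91 and otsB at −0.99 beside otsA. The median was −0.51 for 18 heat shock genes (clpB −1.36, groL −1.08, clpX −0.98, but dnaK 0.95), −0.40 for 19 oxidative stress genes (dps −0.92, sufA −0.83) and −0.62 for 12 genes of the pentose phosphate and Entner-Doudoroff pathways (talA −1.79, edd −1.32), all at percentiles of 0.01 or less. The medians of these lists moved more in the vector than in pSDP10. The median change was −0.05 in pSDP10 and 0.40 in the vector for the RpoS genes, and 0.07 and 0.63 for heat shock. It was −0.10 and 0.15 for oxidative stress, and −0.04 and 0.57 for the pentose phosphate and Entner-Doudoroff list. For otsA, however, the difference came mostly from pSDP10, where its level was 3.01 at 0 min, 0.67 at 30 min, 0.88 at 90 min and 3.83 at 180 min. In all, 189 genes differed by 2-fold or more at 30 min, 134 with a higher and 55 with a lower change in pSDP10. The median difference of all genes was 0.21, so a difference is read relative to that shift. The split depends on the scaling. It was 78 higher and 134 lower with median scaling, 93 and 80 with cyclic loess, 133 and 87 with quantile normalization, and 65 and 166 with scaling to antisense probes of non-coding regions, an alternative chosen after seeing the data.

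At 90 min the hca and mhp genes still had a median of 0.99 (percentile 100, 15 of 15 positive), with hcaF at 1.84, mhpA at 1.82, mhpC at 1.75 and mhpB at 1.47, and marA and marB were at 2.52 and 2.45 (the efflux list as a whole had a median of 0.25, percentile 87.0). The largest positive differences were those of ynfE, an oxidoreductase subunit, at 5.34, rplO at 3.62, secY at 3.54, rplD at 3.20 and the glycerol facilitator gene glpF at 3.20. The level of ynfE had been far lower in pSDP10 than in the vector at 0 min, as given below. Ribosomal protein genes had a median of 1.01, with 27 of 53 at least 2-fold higher (rpmD 2.73, rpsM 2.70). Aerobic respiration genes had a median of 0.82, with all 20 positive (nuoE 2.32, cyoB 1.77), and TCA cycle genes one of 0.65 (sdhA 1.59, sdhD 1.56, sdhC 1.40), each at percentile 100. Alternative carbon uptake had a median of 0.33 (percentile 99.7), with glpA at 2.17 and glpT at 1.84 beside glpF. RpoS genes had a median of −0.68 (percentile 0.0; otsA −3.04, hdeA −2.36, osmC −1.83) and sulfate assimilation genes one of −0.73 (percentile 0.04; cysU −3.37, cysD −2.51, cysJ −2.24), although 6 of these 13 were positive. The median change of the RpoS genes was −0.06 in pSDP10 and 0.56 in the vector.

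The 5 largest negative differences at 90 and at 180 min included genes for zinc and molybdate uptake. At 90 min they were zinT, a periplasmic zinc-binding protein, at −5.87, znuA at −4.43, the molybdate-binding protein gene modA at −4.14, and ykgO and ykgM, which encode alternative ribosomal proteins, at −3.61 and −3.49. At 180 min they were zinT at −5.96, znuA at −4.99, modA at −4.77, ykgO at −4.20 and modB at −4.18. On the 4 vector arrays 3 spots of znuA and 2 of zinT were saturated and kept at their value, so these differences are not exact. The level of zinT in the vector was −1.39 at 0 min, 0.85 at 30 min, 4.45 at 90 min and 4.74 at 180 min, and in pSDP10 it lay between −0.80 and −0.60. For modA the vector levels were −0.47, −0.36, 3.73 and 4.19, and in pSDP10 they lay between −0.32 and −0.15. On the pSDP10 array at 180 min, 7 of 99 other genes at a vector level of 4 or more lay at or below the level of modA, −0.32, the highest of zinT, znuA and modA. In all, 248 genes differed by 2-fold or more at 90 min, 154 higher and 94 lower, and the median of all genes was 0.15. The split was 108 higher and 153 lower with median scaling, 112 and 131 with cyclic loess, and 87 and 200 with scaling to antisense probes.

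**Figure D3:**
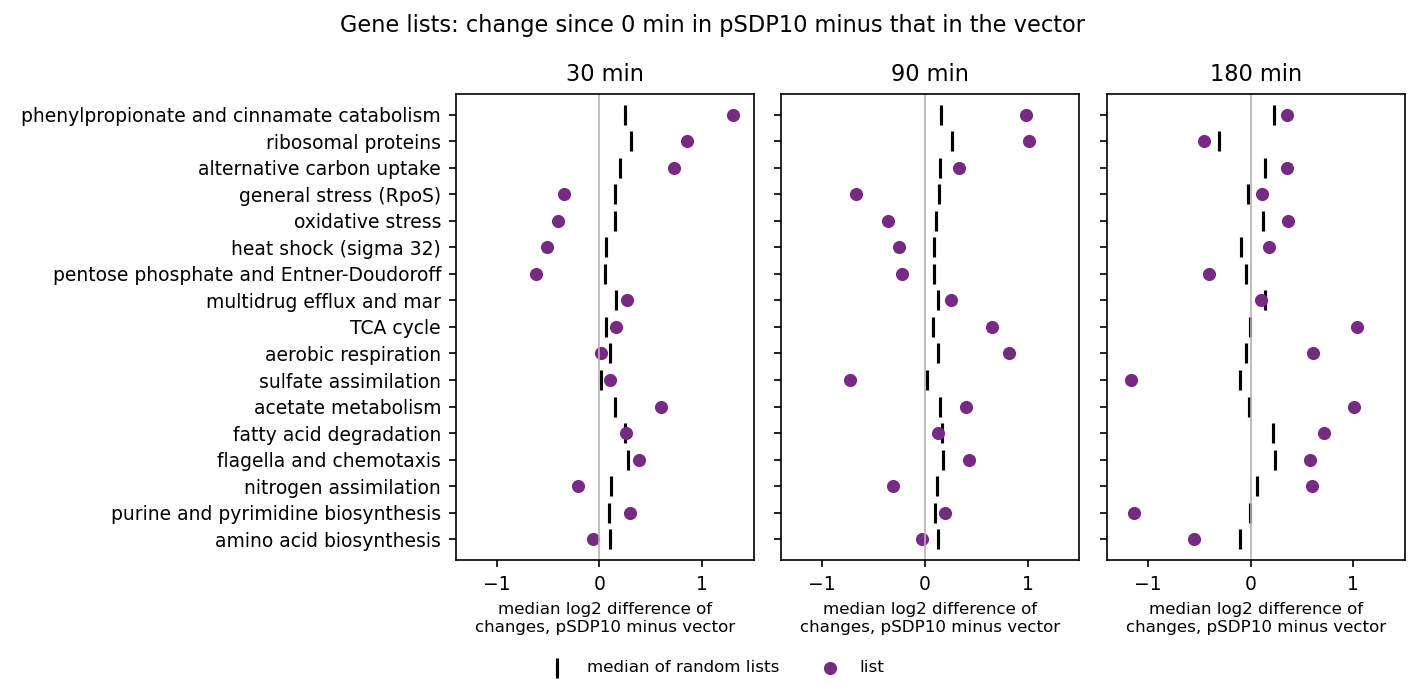
Median difference of changes since 0 min, pSDP10 minus vector (log2), of 17 gene lists at 30, 90 and 180 min. Points are the lists and vertical marks the median of 10000 random lists matched on size and signal; the phenylpropionate and cinnamate list lies at 1.30, 0.99 and 0.36 and the TCA cycle at 0.16, 0.65 and 1.04.

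At 180 min the pattern was another. The hca and mhp genes had a median of 0.36 (percentile 93.8), with none at 2-fold and mhpA at 0.88, mhpB at 0.77 and mhpR at 0.75. The largest positive differences were those of astC at 5.25 and astA at 3.69, of arginine degradation, the methylisocitrate lyase gene prpB at 4.06, rssB, an adaptor in RpoS proteolysis, at 3.95, and sgcB at 3.59. In the vector at 180 min astC (−1.92) and prpB (−1.87) lay below the median of probes antisense to non-coding regions (−1.76), so their differences are not exact. Nitrogen assimilation genes, which include the ast operon, had a median of 0.59 (percentile 100), although gltB, of glutamate synthase, was at −3.11. Their median change was −0.051 in pSDP10, with 9 of 20 positive (percentile 23.4). In the vector it was −0.52, with all 20 negative (percentile 0), so the list's shift was mostly a fall in the vector. TCA cycle genes had a median of 1.04 (16 of 17 positive; sucC 1.60, acnA 1.60, sdhD 1.47), acetate metabolism one of 1.01 (acs 2.93, actP 1.81, yjcH 1.57), fatty acid degradation one of 0.71 (fadL 1.19, fadA 1.09) and flagella and chemotaxis one of 0.58 (motB 1.64, cheA 1.47, fliC 1.47), at percentiles of 99.8 or more. The median change in pSDP10 and in the vector was 0.28 and −0.55 for the TCA cycle and −0.095 and −0.61 for flagella. It was 1.17 and 0.012 for acetate metabolism and 0.38 and −0.34 for fatty acid degradation. Some lists lay on the other side of 0 than at 30 and 90 min. Against the median of all genes, 0.17, the heat shock genes among them were level and the RpoS genes lower by little. Neither list was low against random lists of like signal, whose medians were −0.092 for heat shock and −0.028 for RpoS. Ribosomal protein genes had a median of −0.46 (39 of 53 negative, 13 at least 2-fold lower and 3 higher, percentile 18.5), oxidative stress genes one of 0.36 (percentile 98.2), heat shock genes one of 0.18 (percentile 90.3) and RpoS genes one of 0.11 (percentile 77.0). For nitrogen assimilation the medians at 30 and 90 min had been −0.21 and −0.32, and for purine and pyrimidine synthesis 0.29 and 0.20. The medians of 3 biosynthesis lists were negative. They were −1.16 for sulfate assimilation (12 of 13 negative; cysU −3.94, cysJ −3.41, cysW −3.32), −1.14 for purine and pyrimidine synthesis (18 of 21 negative; purN −2.56, purL −2.21) and −0.55 for amino acid synthesis (trpD −3.61, serA −3.48, trpE −2.99, thrB −2.73), at percentiles of 0.05 or less. The median change in pSDP10 and in the vector was −0.71 and 0.33 for sulfate assimilation. For purine and pyrimidine synthesis it was −0.24 and 0.86, and for amino acid synthesis −0.18 and 0.14. In all, 408 genes differed by 2-fold or more, 201 higher and 207 lower, with a median of all genes of 0.17. The split was 147 higher and 310 lower with median scaling, 234 and 181 with cyclic loess, 281 and 274 with quantile normalization, and 126 and 368 with scaling to antisense probes. The pSDP10 array at 180 min stood apart. Across genes, its levels correlated with those of the other pSDP10 arrays at r = 0.74 to 0.78, against 0.90 to 0.97 among those others. Genes are not independent replicates in these correlations. The pSDP10 array at 180 min and the vector array at 0 min had no multiplicative trend removed, unlike the other arrays. The vector array at 0 min is the baseline of every vector change. Whether this bears on the differences was not tested.

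**Figure D4:**
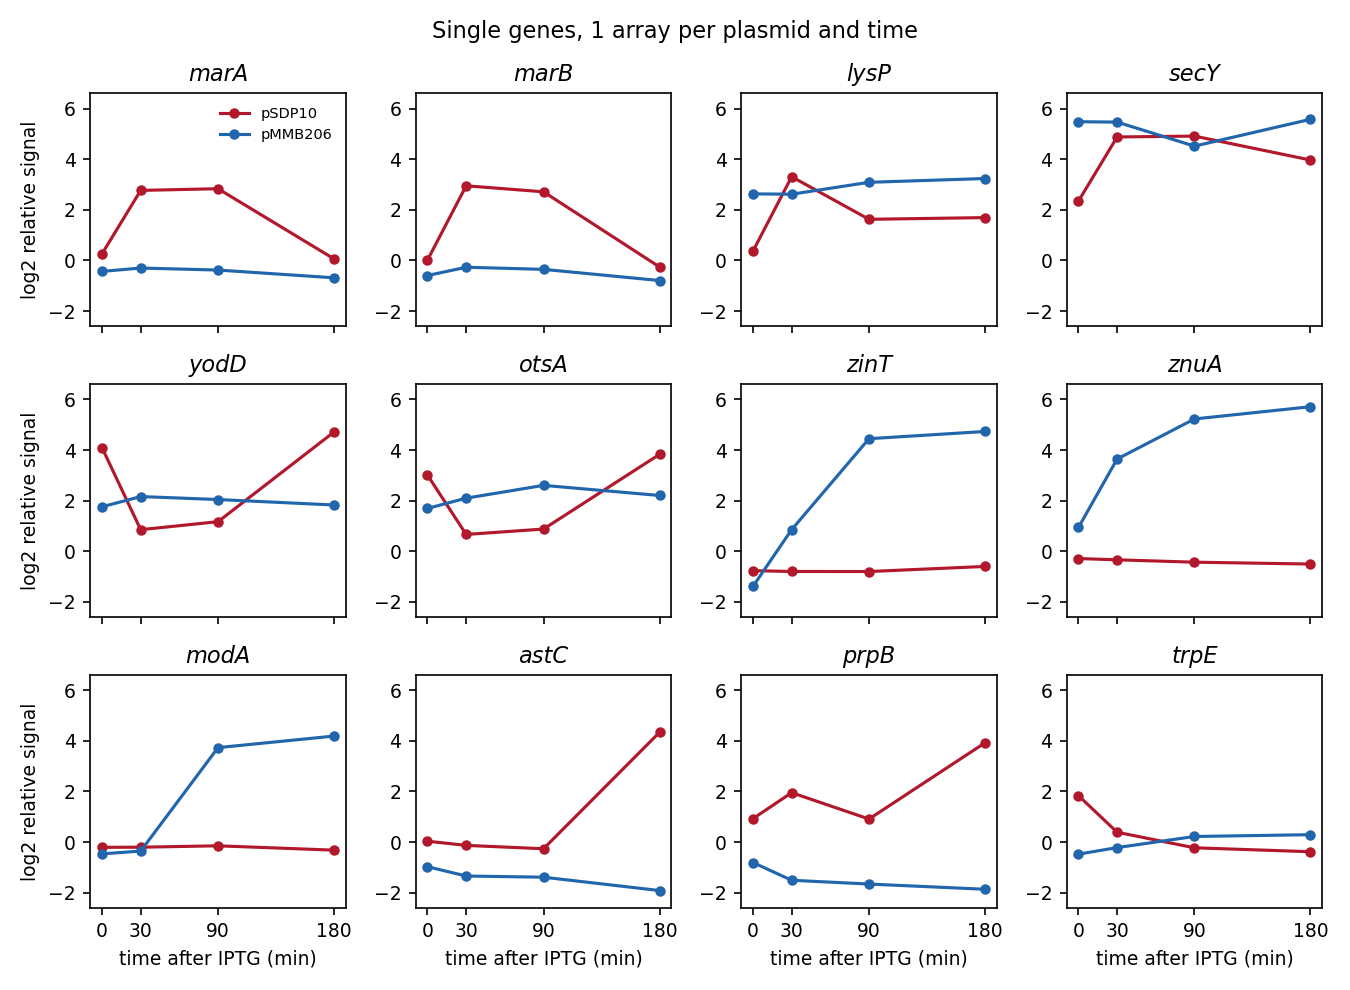
Levels of 12 genes (log2 signal relative to the array's 75th percentile) by time after IPTG in pSDP10 (red) and pMMB206 (blue), 1 array per point. In pSDP10 marA is at 2.77 and 2.84 at 30 and 90 min and at 0.06 at 180 min, and astC is at 4.34 at 180 min only; zinT reaches 4.74 in the vector only.

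The same contrast was tested as the mean of the 3 differences after induction minus the difference at 0 min, with the spread between the 3 later times as its error and 2 residual degrees of freedom. None of the genes named here, by size among those with 1 sign at every time, passed. The highest were ynfE at 2.81 ± 2.09 (SE), secY at 2.54 ± 0.86, acs at 2.40 ± 0.51, prpB at 2.21 ± 1.42, rplO at 2.19 ± 1.07, rpsM at 2.03 ± 0.60, bsmA at 1.96 ± 0.73, ygeX at 1.96 ± 0.38, glpF at 1.95 ± 0.95, astC at 1.86 ± 2.49, dnaK at 1.85 ± 0.81 and tomB at 1.68 ± 0.74. The lowest were zinT at −4.70 ± 1.79, znuA at −4.06 ± 1.00, modA at −3.00 ± 2.15, cysU at −2.87 ± 1.19, trpD at −2.83 ± 0.59, mepM at −2.65 ± 1.43, trpE at −2.48 ± 0.60, aceA at −2.35 ± 0.25, pliG at −2.16 ± 0.68, dnaX at −2.09 ± 0.92, and cysW and cysD, both at −2.02. Saturated spots make some of these values inexact: 9 of acs, 4 of rpsM, 3 of glpF, 2 of secY, 1 of prpB and 1 of astC on the pSDP10 arrays, and 3 each of secY, znuA and dnaK, 2 of zinT, 1 of rpsM and 1 of ynfE on the vector arrays. limma called none of the 4055 genes (0 at an adjusted p under 0.05, lowest adjusted p = 0.443), and 445 had an unadjusted p under 0.05 where 202.75 would be met by chance. In simulated data the same fit called 4.48% of genes with a true log2 difference of 1, 61.2% at 2 and 86.4% at 4.

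By list, all 15 hca and mhp genes were positive in this contrast (median 0.80; mhpA 1.66 ± 0.61, mhpB 1.29 ± 0.41, hcaF 1.27 ± 1.13), although with the rank of time in place of before and after hcaF was at −0.11, with none called over all genes or adjusted over the list alone. The camera set test gave adjusted p = 0.00761 for the list, and adjusted p = 0.821 with an estimated correlation between genes. Alternative carbon uptake (42 of 44 positive, median 0.46; glpT 1.35, rbsD 1.33) and flagella and chemotaxis (38 of 41 positive, median 0.50; fliT 1.61, motB 1.43) were called higher, and so was the TCA cycle (16 of 17 positive, median 0.55; sdhA 1.58, sdhD 1.47), in which 3 genes passed adjusted over the list alone. Each of these 3 calls was lost with an estimated correlation (adjusted p = 0.821 with an estimated correlation). Glycolysis (4 of 21 positive, median −0.33; fbaB −1.17, but aceF 1.07), the RpoS genes (3 of 23 positive, median −0.44; otsA −1.83, but 0.063 with the rank of time, hdeA −1.61), sulfate assimilation (median −0.62) and amino acid synthesis (median −0.14) were called lower. None of the 11 lists called by camera in this contrast was called with an estimated correlation (adjusted p = 0.821 for each) or by fry (lowest adjusted p of the 11 = 0.343). The median of all genes was 0.16. With quantile normalization the glycolysis median relative to all genes changed sign, from −0.49 to 0.10, and with normexp before it to 0.050.

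The second question was which genes changed over time in both plasmids, with the plasmids as the replicates of the time course. The labels give growth at 37 °C and induction at 30 °C, and the sources used here do not say at which temperature the 0 min cells were taken, so a change since 0 min can also hold a change of temperature. The RpoS genes had the largest shift of the lists at 180 min. All 23 were positive, with a median of 1.00, and 10 passed adjusted over the list alone, none over all genes. The median change was 0.89 in pSDP10 and 0.95 in the vector. The acid resistance genes led them, gadB at 3.08 ± 0.29 (SE), gadA at 2.96 ± 0.24 and gadC at 2.28 ± 0.39, with hdeA at 2.34 ± 0.70. Glycolysis genes had a median of 0.55 (18 of 21 positive, 8 passing adjusted over the list alone), with eno at 1.12 ± 0.13, pfkA at 0.97 ± 0.27, ptsI at 0.88 ± 0.20 and pgk at 0.80 ± 0.14, and the list's median was 0.31 in pSDP10 and 0.84 in the vector. In acetate metabolism 3 genes passed adjusted over the list alone (median 0.41; poxB 1.09 ± 0.30, ackA 0.91 ± 0.18), but the list's median was 1.17 in pSDP10 and 0.012 in the vector, where 3 of 6 were positive (percentile 49.3). In mixed-acid fermentation 2 did (median 0.29; adhE 1.47 ± 0.25, pflB 0.80 ± 0.13), with medians of 0.24 in pSDP10 and 0.47 in the vector. All 41 flagella and chemotaxis genes were negative (median −0.37; cheA −0.99 ± 0.39, motB −0.77 ± 0.40), with none passing. Their median was −0.61 in the vector, with all 41 negative, and −0.095 in pSDP10, with 12 positive. Without the vector array at 180 min, gadA, gadB, gadC, eno and ackA passed over all genes, and without the pSDP10 array at 180 min gadA, gadB and gadC did. In these 2 settings the change at 180 min rests on 1 array, with the spread taken from the other times, so these calls carry little weight. Without either array at 90 min, gadA and gadB passed. Over the pSDP10 arrays 2 spots of gadA and 1 of hdeA were saturated, and over the vector arrays 4 of pgk, 3 each of gadA, gadB and ackA and 2 of hdeA. These 5 lists were among 10 called by camera at 180 min (largest adjusted p = 0.000132) and not with an estimated correlation, where adjusted p was 0.295 for the RpoS genes, glycolysis and fermentation, 0.367 for acetate metabolism and 0.787 for flagella. At 30 min 51 of 53 ribosomal protein genes were positive (median 0.73; rplL 1.95 ± 0.52, rplJ 1.35 ± 0.58), with camera adjusted p = 6.01e-17 and adjusted p = 0.516 with an estimated correlation. The median was 1.08 in pSDP10 (percentile 100) and 0.27 in the vector, where matched random lists had 0.20 (percentile 90.7). At 90 min the porin genes had a median of 0.63 (ompC 1.16 ± 0.69, ompT 0.93 ± 0.26), with camera adjusted p = 0.0126 and adjusted p = 0.608 with an estimated correlation, and medians of 0.78 in pSDP10 (percentile 93.7) and 0.29 in the vector (percentile 87.9).

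Gene by gene, limma called 0 of 4055 genes at each of the 3 times. An unadjusted p under 0.05 was met by 197 genes at 30 min, 157 at 90 min and 221 at 180 min, against 202.75 by chance, and the lowest adjusted p was 0.630, 0.799 and 0.0907. No single gene is therefore named beside the lists. A count of 0 does not show that no gene changed, since gadA and gadB, with the values given above, did not pass either. The count at 180 min was 2 without either array at 90 min. It was 21 without the pSDP10 array at 180 min and 152 without the vector array at 180 min, where the change rests on 1 array and the other times give the spread. Across genes, the change since 0 min in pSDP10 correlated with that in the vector at r = 0.20 at 30 min, −0.02 at 90 min and 0.05 at 180 min.

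The third comparison was between plasmids at equal times, in which plasmid and slide are one. The 4 times served as the replicates, with 1 series of arrays per plasmid. The SEs and p-values of this comparison, here and below, therefore measure how steady a difference was over time. They do not measure whether it would recur in other cultures. Higher in pSDP10 over the 4 times were genes of propionate and acetate use, prpD at 4.74 ± 0.47 (SE), prpC at 4.73 ± 0.39, acs, acetyl-CoA synthetase, at 4.57 ± 0.47 and prpB at 3.39 ± 0.64, then the glycerol-3-phosphate dehydrogenase gene glpD at 2.76 ± 0.35, the lactate permease gene lldP at 2.23 ± 0.17, mhpC at 2.22 ± 0.42, phoH at 2.13 ± 0.34, bioA at 2.08 ± 0.23, glcD at 2.08 ± 0.18, ppdD at 2.01 ± 0.14 and ytfJ at 1.96 ± 0.21. Lower were the histidine synthesis genes hisC at −4.68 ± 0.11, hisH at −4.29 ± 0.29 and hisG at −4.20 ± 0.23, rplI at −4.67 ± 0.29, manY at −4.59 ± 0.17 and manX at −4.47 ± 0.16, of mannose uptake, gpmM at −4.36 ± 0.20, adhE at −4.32 ± 0.18, ppc at −4.28 ± 0.23, znuA at −4.27 ± 0.81, leuD at −4.27 ± 0.31 and oppA at −4.17 ± 0.38. A vector level below the median of antisense probes is not exact either, as for prpB at 180 min (−1.87 against −1.76). Saturated spots were kept at their value, so differences of genes that had them are not exact. On the 4 pSDP10 arrays these were 9 spots of acs, 3 of prpC, 2 of prpD and 1 of prpB, and on the 4 vector arrays 11 of oppA, 7 of rplI, 6 of hisC, 3 of znuA, 2 each of manX and manY, and 1 each of hisG, hisH and leuD. Each of these genes had a limma adjusted p of 0.00367 or less, although mhpC did not pass with normexp and quantile normalization (adjusted p = 0.0503).

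By list, 48 of 53 ribosomal protein genes were lower in pSDP10 (median −2.74; rpmC −3.79, rpsU −3.70, rplP −3.68), as were 20 of 21 glycolysis genes (median −2.55; gapA −3.95, fbaA −3.60, ptsH −3.43), all 8 ATP synthase genes (median −2.27; atpG −2.97, atpA −2.85), 40 of 51 amino acid synthesis genes (median −1.89), 15 of 18 heat shock genes (median −1.73; clpX −3.41, ftsH −3.32) and 5 of 6 porin genes (median −3.20; ompF −3.97, ompA −3.82), with 8 spots of clpX and 3 of ompA saturated over the vector arrays and 1 of clpX over the pSDP10 arrays. Higher were all 15 hca and mhp genes (median 1.38; hcaB 1.75, mhpB 1.74), all 17 genes of phenylacetate and aromatic amine catabolism (median 1.24; paaB 1.56, paaA 1.53), 36 of 41 flagella and chemotaxis genes (median 1.09; motA 1.63, trg 1.48), 25 of 27 iron uptake genes (median 1.01; entA 1.73, fes 1.42) and 20 of 22 prophage genes (median 1.13; ydfB 1.47, ydfD 1.42). Adjusted over the list alone the counts were 49 lower for ribosomal proteins, 37 higher for flagella and as given for the others. With cyclic loess clpX no longer passed, and with quantile normalization hcaB did not. Camera called these 11 of 22 called lists (largest adjusted p of the 11 = 0.0144), and with an estimated correlation none (adjusted p = 0.348 for glycolysis, amino acid synthesis and porins, 0.499 for ribosomal proteins and heat shock, 0.517 for ATP synthase and 0.670 for the 5 higher lists). Nitrogen assimilation was called lower although its median was 0.058 (mean −0.54; camera adjusted p = 0.0356, and adjusted p = 0.670 with an estimated correlation).

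The direction went with the level of the gene. Of the 811 genes with the lowest mean levels over all 8 arrays 761 were called higher and 5 lower, and of the 811 with the highest 42 were called higher and 575 lower. Across genes, the difference correlated with the mean level over all arrays at r = −0.71. A narrower range of levels in pSDP10 gives a negative correlation by itself, and the SD of levels across genes was 0.781 to 0.939 on the pSDP10 arrays and 1.44 to 1.66 on the vector arrays. In all, limma called 3194 of 4055 genes, 2210 higher and 984 lower, of which 1556 differed by 2-fold or more, and the median of all genes was 0.47. Quantile normalization left 2301 (1345 higher and 956 lower), cyclic loess 2051 (1087 and 964), median scaling 2899 (1153 and 1746) and scaling to antisense probes 2689 (645 and 2044), so the split depends on the scaling. Of the 3194 genes, 1917 were also called with quantile normalization in the same direction and 1502 with cyclic loess.

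**Figure D5:**
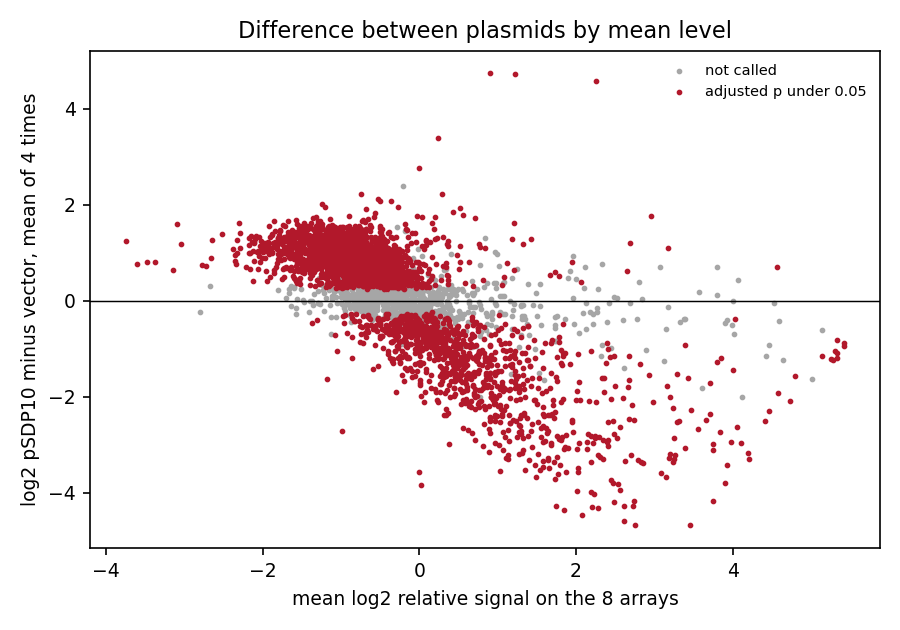
Difference between plasmids, pSDP10 minus vector (log2, mean of the 4 times), of each of 4055 genes against its mean level on the 8 arrays (log2 signal relative to the 75th percentile). Red points have an adjusted p under 0.05 and grey points do not; most genes of low mean level lie above 0 and most of high mean level below it, with r = −0.71 across genes.

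Much of this difference was there before induction. At 0 min prpD was 3.63 higher in pSDP10, prpC 3.59, acs 2.77, glpD 2.50 and lldP 2.46, while ynfE was at −5.12, rplI at −4.90, leuD at −4.72, the elongation factor gene fusA at −4.67 and ompF at −4.62, with 10 spots of fusA saturated over the vector arrays. Against random lists of like signal, iron uptake genes were high (median 0.97, percentile 100, all 27 positive; fes 2.02, entA 1.77, tonB 1.76), as were those of phenylacetate catabolism (1.11, percentile 99.8; paaA 1.45, paaZ 1.39), while the hca and mhp genes (0.78, percentile 92.7; mhpF 1.51, hcaR 1.10) were not beyond the 95th percentile. Ribosomal proteins (−2.80; rpmC −4.55), glycolysis (−2.49; gpmM −4.01, gapA −3.95), amino acid synthesis (−1.83; hisG −4.58) and porins (−3.10; ompA −4.32) lay at percentiles of 1.45 or less. Heat shock genes were at percentile 2.34 and prophage genes at 96.4. Flagella and chemotaxis genes (0.59, against 0.70 for random lists, percentile 11.0) and ATP synthase genes (−2.31, percentile 6.9) stood out less from lists of like signal. A 2-fold difference was met by 1069 genes, 522 higher and 547 lower, with a median of all genes of 0.35. With median scaling 938 genes met it, 68 higher and 870 lower, with scaling to antisense probes 1027, 40 higher and 987 lower, and with cyclic loess 477, 192 higher and 285 lower.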

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

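The tests of an aberrant array, of saturation, of slide and batch and of random lists, and the levels set against a narrow range for the third pattern, were chosen after the results were seen, and the others in this part before. Each difference between plasmids in the change after induction given here for a gene was not tested, or did not pass its test. The hca and mhp list and alternative carbon uptake were called by camera (adjusted p = 0.00761 and 0.00493). With an estimated correlation camera called neither (adjusted p = 0.821 for both). The changes of a plasmid share 1 array at 0 min.

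Some lists and genes were singled out because the changes on the 3 later pSDP10 arrays, relative to all genes, had one sign and those on the 3 vector arrays the other, in some cases by little (0.0069 for hca and mhp in pSDP10 at 180 min, −0.015 for alternative carbon uptake in the vector at 90 min). The mean difference of changes relative to all genes was 0.79 for the hca and mhp list and 0.36 for alternative carbon uptake. It was 2.66 for ynfE, 1.81 for bsmA, 1.81 for ygeX, −4.21 for znuA, −2.98 for trpD, −2.80 for mepM, −2.63 for trpE, −2.50 for aceA, −2.23 for dnaX and −2.17 for cysD. The tryptophan synthesis genes went from levels of 1.83 (trpE) and 1.66 (trpD) in pSDP10 at 0 min to −0.38 and −0.65 at 180 min. For the contrast of changes, taking another time as the baseline gave up to 86 called genes (180 min) against 0 with 0 min. The 4 possible baselines, all with at least as many genes as the real one, are too few for a share under 0.05.

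Data outside the comparisons also held signal. Of the 2190 probes antisense to non-coding regions, 98.3% to 99.6% were well above background on the 8 arrays. Their median signal was 810 to 1396 on the pSDP10 arrays and 278 to 447 on the vector arrays, against 1.32 to 2.46 for 77 negative control spots.

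The first pattern weighed is the narrow range of signal on the pSDP10 arrays. A difference in the overall spread of signal does not alone account for all of the 3194 genes called between plasmids. Of these, 1917 were also called in the same direction with quantile normalization, which gives all arrays the same distribution of signal. It keeps the order of probes within an array, so a cause of the narrow range that changes this order is not excluded for these genes. Detector saturation is argued against, since no pSDP10 array had over 56 saturated spots and no vector array under 72. Of 32 splits of the 8 arrays into 4 and 4 that could be fitted 1 gave as many genes, the real one, and the highest other gave 0. Every other split mixes arrays of both slides, so the difference between slides enters its error and few calls can be met. This count therefore cannot exclude a chance split. Genomic DNA in the labelled material stays open, since signal correlated with probe GC over antisense probes at 0.264 or more on the pSDP10 arrays and at up to 0.280 on the vector arrays, which met the bound set beforehand to exclude it, but by less than the spread of the pSDP10 arrays (0.264 to 0.283), a condition added after the result was seen. Slide, scan day and labelling cannot be told apart from the plasmid, because each slide held 1 plasmid and the ratio of the 95th to the 5th percentile was at most 11.7 on 1 slide and at least 44.0 on the other, and a true effect of carrying pSDP10 was not tested apart from these.

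The second pattern is the higher level of the hca and mhp genes in pSDP10 at 30 and 90 min. Scaling is argued against, since over the scaling alternatives the contrast between plasmids relative to all genes was never under 0.84 at 30 or 90 min. Median scaling shifts all genes of an array alike and so cannot change this value, and the authors' table was scaled as the main values. Only quantile normalization, with and without normexp, and cyclic loess therefore bear on it. A general rise of genes of this signal is argued against, since random lists of the same size and signal had a median pSDP10 change of at most −0.030 at both times. An aberrant pSDP10 array at 0 min stays open, since the value that speaks against it, a list median at 180 min of 0.0069 relative to 0 min and all genes, rests on the 1 pSDP10 array that stood apart. A response to Orf306 or to its products may account for the pattern, as may a difference between 2 single cultures, which the design leaves open.

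The third pattern is the metal uptake genes on the vector arrays. A single aberrant vector array is argued against, since the 5 zinc and molybdate genes picked at 180 min were a median of 3.64 higher at 90 than at 30 min, and the 5 picked at 90 min 4.16 higher at 180 than at 30 min. A pSDP10 range too narrow to show such levels stays open, since of 99 other genes at a vector level of 4 or more at 180 min 7.07% lay on the pSDP10 array at or below the highest of zinT, znuA and modA, above the 5% that had been set as the bound. Against it, the other 92 lay above, with a median of 1.18 over all 99, and the highest level of any gene on that array was 4.72, where zinT, znuA and modA had 4.19 to 5.71 in the vector. A difference in trace metals between the cultures was not tested.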

How the results depend on the processing

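Scaling to antisense probes and times up to 90 min only were alternatives chosen after seeing the data, and all others before. Over all settings 4851 single values stayed the same, 93 without a test moved, 12 gained and 15 lost a call, and 10 reversed. A tested gene stayed the same if it kept its direction and side of the threshold. An untested difference did if it moved by 1 or less on the log2 scale, and its change of sign counted only from a main value of 1. A list median did if it kept its sign relative to all genes and moved by no more than the SD of its genes. The 4851 include 353 for each filter on dim probes, 353 for the authors' table, which was scaled as the main values, and 352 for median scaling. Median scaling shifts all genes of an array alike, so it cannot move a list median relative to all genes. The total therefore says little about stability. Of the counts of genes and lists 4 grew, 5 shrank and 9 without a test moved. The 3194 genes called between plasmids became 2051 with cyclic loess and 1556 at 2-fold or more, and 2892 to 3125 with 1 array left out. For the time contrasts and the contrast of changes no alternative scaling, filter or design called a gene, and leaving out an array gave 0 to 152 genes at 180 min and 0 elsewhere, but without an array at 180 min the change rests on 1 array and the other times give the spread. The genes past a fold between plasmids were, at 1.5-fold and 3-fold, 676 and 62 at 30 min, 691 and 95 at 90 min, 928 and 179 at 180 min, and 2245 and 392 before induction, where cyclic loess gave 477 at 2-fold. Camera called 79 lists over the 5 contrasts, 52 with cyclic loess and 0 with an estimated correlation, and fry, which does not compare a list with other genes, called 26, all between plasmids and not all among camera's. With the rank of time in place of before and after, the contrast of changes reversed for hcaF (−0.11), otsA (0.063), osmC (0.041) and osmY (0.20), and the glycolysis median relative to all genes reversed with quantile normalization (0.10) and with normexp before it (0.050). With 1 array left out, the change at 180 min was −1.45 to 0.10 for flgD, −0.18 to 1.02 for yjcH and −0.11 to 1.18 for hycE, each changing sign. Fold minima and fewer arrays change the counts by construction, and otherwise the cause was not tested. The filters on dim probes removed no tested gene, so they say nothing about stability. The contrast of changes could not be fitted without either array at 0 min, and a slide block could not be fitted between plasmids. The plasmids were paired by time in the fits, and a block by replicate number was not possible because each group holds 1 sample. The background flag sets no useful limit, since 98.3% to 99.6% of antisense non-coding probes also passed it, and on the pSDP10 arrays the coding median was 0.58 to 0.63 above theirs on the log2 scale, so low levels there are uncertain.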

Other observations

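The test of the zinc and molybdate regulons was chosen before znuB, znuC and modC were seen, and the gene groups of this part after single members had been seen. The ast operon of arginine degradation was high on 1 array only. In pSDP10 at 180 min the 5 genes astA to astE had a median change since 0 min of 2.77 and in the vector one of −0.40, with astC at 4.34, astE at 3.03, astA at 2.80, astB at 1.97 and astD at 1.12 in level, and at 30 and 90 min no ast gene in pSDP10 was above 0.16. The propionate genes in pSDP10 had levels of 2.64, 3.60, 2.17 and 4.67 (prpD) and 0.93, 1.95, 0.91 and 3.92 (prpB) over the 4 times, and in the vector no prp gene was above −0.72, while prpE at 180 min was at 0.68 and the regulator gene prpR at −0.60.

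A second group, otsA, otsB, yodD, ytjA, osmB, osmC and osmY, was gathered after low values at 30 min had been seen, so a low median there comes with the choice. The median change since 0 min in pSDP10 was −1.24 at 30 min, −0.98 at 90 min and 1.23 at 180 min, and in the vector it was 0.51, 0.85 and 0.92. The member osmB did not share the low values, with changes in pSDP10 of −0.026 at 30 min and 0.0072 at 90 min. At 30 and 90 min yodD was at 0.85 and 1.17 in pSDP10, between 4.09 at 0 min and 4.72 at 180 min. The marA and marB levels had the opposite course.

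A hypothesis from the named genes was that the whole zinc (Zur) and molybdate (ModE) regulons moved in the vector cells. It may hold only in part. The 8 zinc genes and the 3 molybdate genes had median vector changes of 3.72 and 4.04 at 180 min, and −0.06 and −0.11 in pSDP10. Of the 3 members not named by the rule, modC went from −1.59 to 0.15 and 0.47 at 90 and 180 min, and znuC from −1.34 to −0.49 and 0.06. The smallest vector change among these was 0.39 (znuB at 90 min), under the bound of 1 that had been set. All 11 genes had positive vector changes at both times.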
